A study of Mus musculus with 24 samples.

How the data were processed

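RNA of mouse liver was hybridized to 24 Affymetrix 3' arrays, per the labels, with 3 arrays in each of 8 groups: young and adult mice after a sham operation or after 30, 60 or 90 min of partial hepatic ischemia. Per the labels, the values were made with RMA, with no version given. The deposited values are linear ratios, and in the files the arithmetic mean of the 3 sham ratios of an age is 1 for each of the 26180 probe sets, within 2e-07, in young and in adult mice. Each age was therefore scaled to its own sham arrays before the files were deposited. Adult and young sham livers cannot be compared, and array brightness is not kept.

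Groups were taken from the sample labels alone. The comparisons, the tests, the gene lists and the rule for named genes were chosen before the data were examined. RefSeq accessions were paired with symbols from the supplied table: 15228 probe sets had 1 symbol and 10952 had none, 10357 of the latter being predicted accessions. For the 661 genes with more than 1 probe set, 1 was chosen without looking at values, by type of accession and then by the lowest accession number. This left 14351 genes. The planned filters on dim probe sets, the choice of the probe set with the highest mean, the variance trend and the comparison of adult with young sham liver need brightness and were not run. No probe set stood for Hspa1b.

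The log2 ratios were fitted in limma 3.58.1 (R 4.3.3) with 8 group means, 16 residual degrees of freedom and the default prior (4.53 degrees of freedom). A gene passed at an adjusted p under 0.05 (Benjamini-Hochberg over genes within a comparison, two-sided). Each ischemia time was compared with sham of its age, the adult response was compared with the young response at each time, and the 3 times were also tested together. The 27 lists, of which 9 hold cell type markers, were tested in each of 9 comparisons with camera at a preset correlation of 0.01, with adjustment over all 243 tests. Camera with an estimated correlation and fry stand beside it. Camera ranks a list against all other genes, whereas fry asks whether its genes changed at all. Counts of list members are given over all genes and adjusted over the list alone. Responses of the ages were also correlated across genes.

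Genes are named by rule: the 8 largest rises and the 8 largest falls among genes that passed and whose groups of 3 do not overlap, up to 4 members per list with the largest change, and a short set of ischemia, proteasome and liver genes. Of the genes the rule names, 2 are not reported here. Genes outside the rule are said to be chosen after their values were seen. An error is the standard error of the log2 fold change from limma unless SD is written.

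Alternatives were every probe set on its own, quantile normalization, the first part of the title code as a block, array weights, log2(ratio + 16), the arrays of 1 age only and each array left out in turn. As the values are ratios near 1, log2(ratio + 16) is nearly linear in the ratio. It stretches rises against falls and does not damp dim probe sets. After the data were seen, the mean of a gene's probe sets, arrays centred on their median, a robust prior, the number in the second part of the title code as a covariate and comparisons between ischemia times were added. Array weights were estimated gene by gene, because the default method stopped before converging and gave 1 array a weight of 31.9; its counts had been seen by then. On simulated data with 100 genes changed at each size, 94% of genes set to a log2 change of 1 and 99% of those set to 2 were found for adults at 60 min, with 21 unchanged genes also called. For the age difference at 60 min 82% and 100% were found, with 8 unchanged genes called. With no change set, 0 genes and 0 lists were called. Real arrays put into other groups gave up to 391 genes for adults at 30 min and 998 for the age difference at 60 min. The simulated rates may therefore not hold for the real arrays. They also do not show that the list test with the preset correlation is safe there, as 0 of its 108 calls passed with an estimated correlation.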

Results

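Liver transcripts were measured on 24 Affymetrix 3' expression arrays from young mice, 4 to 5 weeks old, and adult mice, 12 to 14 months old. Each age gave 12 arrays: 3 after a sham operation and 3 after each of 30, 60 and 90 min of partial hepatic ischemia, in which the blood supply of part of the liver is closed. The sample titles write the ischemia times as 30/0, 60/0 and 90/0. The second part could be a time of restored blood flow before the tissue was taken, but the labels do not say what it stands for. They name the median and left lobes as the tissue. The deposited values are ratios to the mean of the 3 sham arrays of the same age, so that this mean is 1 for every probe set in either age. They ran from 0.0255 to 16.9, and the median ratio of an array lay between 0.956 and 1.02. The ratios keep no array brightness, so the precision of each value is limited by the number of arrays, 3 per group. The number in the second part of the code in the sample titles was 5 for 5 of the 6 sham arrays and differed between most groups. The questions the design poses are which genes respond to ischemia of each length in each age, and whether the responses differ between the ages. Whether sham liver differs between the ages cannot be read from these ratios.

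After 30 min in young mice, Slc25a25, a mitochondrial carrier of ATP-Mg and phosphate, rose by a log2 value of 1.89 ± 0.35 (SE, n = 3 per group; adjusted p = 0.0467), to a mean ratio of 3.49 ± 0.605 (SD, n = 3). Cyp2b10, a cytochrome P450 induced through the nuclear receptor CAR, fell to a mean ratio of 0.0641 ± 0.0256 (SD, n = 3) against 1 ± 0.241 in sham liver, a log2 value of -4.01 ± 0.73 (adjusted p = 0.0405). Gpcpd1, a glycerophosphocholine phosphodiesterase, fell by 1.99 ± 0.27, and Gja4, the gap junction protein connexin 37 of arterial endothelium, fell by 1.14 ± 0.16. Both had an adjusted p of 0.00389. The autophagy gene Atg14, the endosomal Rab5 exchange factor Rabgef1, the AP-1 member Fosl2 and the lysophospholipase D Enpp2 (autotaxin) fell by 0.97, 0.72, 0.63 and 0.62. In each of these 8 genes the 3 ischemia arrays did not overlap the 3 sham arrays, as the rule for naming them asks. The arrays of either group did not overlap in 14.8% of all genes, where chance gives 10%. Of the 14351 genes tested, these 8 passed in limma, 1 up and 7 down, and 1200 had an unadjusted p under 0.05. The lists of genes fixed in advance showed shifts that passed the test with a preset correlation only. The 28 cytochrome P450 genes had a mean log2 value of -0.39 (adjusted p = 4.79e-07, and adjusted p = 0.605 with an estimated correlation), with 1 of 28 falling over all genes and 3 when adjusted over the list alone. With any 1 of the 6 arrays left out 0 fell over all genes; over the list alone 1 fell without young sham replicate 2 or young 30 min replicate 3, and 6 without young 30 min replicate 2. The 32 cell cycle genes had a mean of 0.32 (adjusted p = 1.39e-11, and adjusted p = 0.514 with an estimated correlation), with 0 of 32 passing either way. This rise came largely from 1 array: the list mean was 0.73 in young 30 min replicate 1, against 0.09 and 0.06 in replicates 2 and 3. Young sham replicate 3 was at 0.17. With any 1 of the 6 arrays left out Gpcpd1, Gja4, Rabgef1 and Fosl2 still passed, and the other 4 genes each lost the call without at least 1 array. The count was 4 without young 30 min replicate 1 and 5 without young 30 min replicate 3. It was 5 on log2(ratio + 16), 46 in a fit to the young arrays alone and 304 with array weights.

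After 60 min in young mice, Inhba, the activin A subunit, rose by 0.98 ± 0.17 on the log2 scale (adjusted p = 0.0468), and Prox1, a homeobox factor of hepatocytes and lymphatic endothelium, rose by 0.78 ± 0.10 (adjusted p = 0.00403). Gja4 fell by 1.15 ± 0.16 (adjusted p = 0.00548), and Ednrb, the endothelin B receptor, fell by 0.56 ± 0.10 (adjusted p = 0.0468), with a mean ratio of 0.68 ± 0.0275 (SD, n = 3) against 1 ± 0.016 in sham liver. Hepatic stellate cell markers, which belong to the vitamin A-storing pericytes of the sinusoids, had a mean log2 value of -0.38, with 11 of 12 below 0. None of the 12 passed over all genes and 6 fell when adjusted over the list alone (list test adjusted p = 2.54e-06, fry adjusted p = 0.0272, and adjusted p = 0.274 with an estimated correlation). Among them, Colec11 was at -0.88 and Rgs5 at -0.67. Markers of Kupffer cells, the resident macrophages of the liver, had a mean of -0.53 with 13 of 13 below 0 (adjusted p = 1.85e-05, and adjusted p = 0.696 with an estimated correlation). None of the 13 passed over all genes and 4 fell when adjusted over the list alone, a number that was 0 without young sham replicate 3 or young 60 min replicate 1. The 38 olfactory receptor genes, which liver is not known to use, had a median of 0.10 on the same arrays, above the medians of 1000 random sets of the same size, the highest of which was 0.07. In all 4 genes passed in limma, 2 up and 2 down, and 1498 had an unadjusted p under 0.05. With each array centred on its median the split was 2 up and 1 down. Prox1 passed with any 1 of the 6 arrays left out, and the other 3 genes each lost the call without at least 1. The count was 1 without young sham replicate 2 or young 60 min replicate 1, and 2 without young sham replicate 1 or young sham replicate 3. It was 2 with the first part of the title code as a block and 30 with array weights.

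After 90 min in young mice, 5 of 12 markers of hepatic stellate cells fell over all genes and 9 when adjusted over the list alone, among them Colec11, a collectin, by 1.04 ± 0.18 on the log2 scale, Rgs5, a regulator of G protein signalling in pericytes, by 1.02 ± 0.20, Reln (reelin) by 0.81 ± 0.16 and the matrix protein gene Ecm1 by 0.78 ± 0.15. All 12 were below 0, with a mean of -0.53 (list test adjusted p = 2.80e-12, fry adjusted p = 0.00287, and adjusted p = 0.0852 with an estimated correlation). Markers of other non-parenchymal cells were low on the same arrays, Kupffer cells at a mean of -0.37 with 11 of 13 below 0 and endothelial cells at -0.22 with 12 of 14 below 0 (adjusted p = 0.00163 and 0.0202, and adjusted p = 0.696 for both with an estimated correlation). None of these passed over all genes. Ednrb fell by 0.85 ± 0.10 (adjusted p = 0.000365), the lowest adjusted p of this comparison. Cyp2b10 fell by 3.95 ± 0.73, Gpcpd1 by 1.48 ± 0.27, the muscle-enriched gene Mustn1 by 1.11 ± 0.19, Gja4 by 0.90 ± 0.16 and the matrix proteoglycan Prelp by 0.82 ± 0.15. Genes that rose included Chka, choline kinase alpha, by 1.20 ± 0.20, and Prkaa2, a catalytic subunit of the energy sensor AMPK, by 0.95 ± 0.15. Zdhhc21, G3bp2, Rcor1, Dync1h1 and Kif1b rose by 0.95, 0.90, 0.78, 0.68 and 0.64, and a second probe set of Kif1b was at -0.08. The matrix genes Lum, at -0.96 (adjusted p = 0.0593), and Bgn, at -0.58 (adjusted p = 0.0593), missed the threshold. The 32 cell cycle genes had a mean of 0.32 (adjusted p = 2.25e-09, and adjusted p = 0.606 with an estimated correlation), led by Cdc20 at 1.27 and Mcm6 at 0.95. Of these 0 of 32 passed over all genes or when adjusted over the list alone. Sterol and fatty acid synthesis had a mean of 0.12 over 24 genes, of which 0 passed either way (adjusted p = 0.0491, and adjusted p = 0.737 with an estimated correlation). It lost the call with every probe set on its own (adjusted p = 0.110) and with arrays centred on their median (adjusted p = 0.0715). With the title code number as a covariate its direction turned (adjusted p = 0.960). In limma 26 genes passed, 10 up and 16 down, and 1292 had an unadjusted p under 0.05. The balance of rises and falls turned with the processing: it was 4 up and 20 down after quantile normalization, 15 up and 6 down on log2(ratio + 16), 9 up and 7 down with the title code number as a covariate, 3 up and 1 down with the first part of the title code as a block, and 470 up and 399 down with array weights. The scale of log2(ratio + 16) by itself favours rises over falls. Of the 17 values named here that passed, that of Ednrb alone passed with any 1 of the 6 arrays left out. The count was 2 without young sham replicate 1, young sham replicate 2 or young 90 min replicate 1, 3 without young 90 min replicate 2, and 11 without young sham replicate 3. It was 52 without young 90 min replicate 3. The 5 stellate markers became 0 with any 1 array left out except young 90 min replicate 3, while 7 to 9 still fell when adjusted over the list alone. The count was 4 with the first part of the title code as a block, 16 with its second part as a covariate, 66 in the young arrays alone and 869 with array weights.

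After 30 min in adult mice no single gene passed. Cyp2b10 was at -2.85, the neutrophil chemokine Cxcl1 at -2.20 and the metallothionein Mt2 at -2.48 on the log2 scale, while Jun was at 1.34 and Fos at 1.33. Markers of T and NK cells had a mean of 0.20 with 16 of 16 above 0 (list test adjusted p = 5.69e-07, fry adjusted p = 0.0272, and adjusted p = 0.195 with an estimated correlation). Among them Ccl5 was at 0.52 and Gzmb, granzyme B, at 0.41. None of the 16 passed over all genes and 5 rose when adjusted over the list alone. That number was 0 without adult sham replicate 1, adult sham replicate 3, adult 30 min replicate 1 or adult 30 min replicate 3, and 8 without adult sham replicate 2. Kupffer cell markers had a mean of -0.52 with 13 of 13 below 0 (adjusted p = 4.28e-05, and adjusted p = 0.696 with an estimated correlation), which was -0.22 without adult sham replicate 3. None of the 13 passed over all genes and 1 fell when adjusted over the list alone. In limma 0 of 14351 genes passed, and 1485 had an unadjusted p under 0.05. The count was 33 without adult sham replicate 2 and 89 without adult 30 min replicate 3, and 2350 with array weights, which gave adult 30 min replicate 2 a weight of 4.8 and adult 30 min replicate 3 a weight of 0.256.

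After 60 min in adult mice, 22 of the 41 measured genes of the proteasome, the complex that degrades ubiquitin-tagged proteins, fell over all genes. Of the 41, 33 fell when adjusted over the list alone, and 40 were below 0, with a mean log2 value of -0.52. Psma1, Psmd7 and Psmc6 fell by 0.86 ± 0.19, 0.79 and 0.79, Psma1 to a mean ratio of 0.557 ± 0.102 (SD, n = 3) against 1 ± 0.0782 in sham liver. Psmd1 also fell, by 0.55, whereas Psmb5, at -0.31, had an adjusted p of 0.0644. The list test gave adjusted p = 3.25e-10 and fry adjusted p = 0.0431, with adjusted p = 0.696 with an estimated correlation. On the same arrays, the 38 olfactory receptor genes had a median of 0.11, and this value stands beside each group named here. Hepatocyte markers had a mean of -0.29 with 17 of 17 below 0, and Kupffer cell markers one of -0.54 with 13 of 13 below 0, which was -0.24 without adult sham replicate 3 (adjusted p = 0.0005 and 0.0138, and adjusted p = 0.696 and 0.702 with an estimated correlation). Of the hepatocyte markers 3 fell over all genes and 7 over the list alone, numbers that were 11 and 16 without adult 60 min replicate 1 and at most 1 and 3 without any of the other 5 arrays.

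In the same adult livers at 60 min, 8 of 19 heat shock proteins and co-chaperones fell over all genes and 14 when adjusted over the list alone, with a mean of -0.53, among them Hsp90aa1 by 1.21 and Dnaja1 by 0.87 (list test adjusted p = 0.000131, fry adjusted p = 0.0564, and adjusted p = 0.696 with an estimated correlation). Of 22 genes of endoplasmic reticulum stress 4 fell over all genes and 8 when adjusted over the list alone, with 1 rising. The chaperone Hspa5 (BiP) fell by 1.13 ± 0.30 and Manf by 1.08 (list test adjusted p = 0.00822, fry adjusted p = 0.136, and adjusted p = 0.696 with an estimated correlation). Of 26 antioxidant and glutathione genes 12 fell over all genes and 18 when adjusted over the list alone, among them the glutathione transferases Gsta2 by 1.18 and Gstm3 by 1.00 (adjusted p = 4.53e-06, fry adjusted p = 0.0272, and adjusted p = 0.688 with an estimated correlation). Of 28 cytochrome P450 genes 9 fell over all genes and 16 when adjusted over the list alone, with Cyp2b10 by 3.44 ± 0.73, Cyp2c55 by 1.17 and Cyp3a13 by 0.87 (adjusted p = 2.91e-05, fry adjusted p = 0.0303, and adjusted p = 0.696 with an estimated correlation). Oxidative phosphorylation had 13 of 48 genes falling over all genes and 34 when adjusted over the list alone, Uqcrc2 by 0.70 among them, and 48 of 48 were below 0 (mean -0.44; adjusted p = 4.42e-09, and adjusted p = 0.696 with an estimated correlation).

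Among single genes in adults at 60 min, Cxcl1 fell by 2.63 ± 0.54, Srp54a, a gene for the signal recognition particle protein SRP54, by 2.10, and the tubulin gene Tubb2a by 1.69. Further falls were those of the bile acid transporter Slc10a2 by 1.43, of the lipogenic factor Thrsp by 1.36 and of the ubiquitin ligase gene Hectd2 by 1.28. The kinase gene Sgk1, a glucocorticoid target, fell by 1.25. Genes that rose were led by Adam6b, by 1.88 ± 0.47, Impdh2, which makes guanine nucleotides, by 1.16, Vwc2 by 1.13, Vat1 by 1.12 and Psd3 by 1.07. Others were the angiogenin family ribonuclease Ang2 by 1.03, the noncoding RNA Dio3os by 1.01 and 1700020L24Rik by 1.00. Tnf, the tumor necrosis factor, rose by 0.42 (adjusted p = 0.0435), and Jun, at 1.37, had an adjusted p of 0.0644. In limma 1712 genes passed, 309 up and 1403 down, and 4773 had an unadjusted p under 0.05. Centring each array on its median gave a split of 432 up and 968 down. The 3 arrays of either group did not overlap in 37.0% of genes, where chance gives 10%.

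The adult count at 60 min depended on single arrays: it was 14 without adult sham replicate 1, 588 without adult sham replicate 2, 4 without adult sham replicate 3, 23 without adult 60 min replicate 2 and 1 without adult 60 min replicate 3. The 22 proteasome genes became 0, 9, 0, 1 and 0 over all genes, and 33, 28, 27, 29 and 22 fell when adjusted over the list alone. With the same arrays left out 1 at a time, 0 to 2 of the 8 heat shock genes, 0 or 1 of the 4 endoplasmic reticulum genes, 0 to 6 of the 12 antioxidant genes, 0 to 4 of the 9 cytochrome P450 genes and 0 or 1 of the 13 oxidative phosphorylation genes passed over all genes. Without adult 60 min replicate 1, 3 heat shock, 14 cytochrome P450 and 22 oxidative phosphorylation genes passed, and 8 heat shock genes passed over the list alone. Over the list alone, adult 60 min replicate 3 left 0 endoplasmic reticulum, 1 antioxidant, 3 cytochrome P450 and 0 oxidative phosphorylation genes. Adult sham replicate 1 left 3, 11, 6 and 15 of them, adult sham replicate 2 left 9 oxidative phosphorylation genes, and adult sham replicate 3 left 0 endoplasmic reticulum genes. None of the 29 single genes tracked across settings passed with each of the 6 arrays left out. The fold changes moved less: with any 1 of the 6 arrays left out the 1712 genes kept a median of 89.3% to 108% of their log2 values, all with the same sign, and 1685 to 1711 of them had an unadjusted p under 0.05. Quantile normalization left 0 genes (1486 at an unadjusted p under 0.05), log2(ratio + 16) left 465 and the adult arrays alone 587, while array weights gave 2924 and the title code number as a covariate 3200.

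After 90 min in adult mice, markers of Kupffer cells fell. Of 13 measured markers 12 fell, over all genes as when adjusted over the list alone, and 13 of 13 were below 0 with a mean log2 value of -1.17. Cd163, the haptoglobin-hemoglobin scavenger receptor, fell by 1.84 ± 0.25 (adjusted p = 0.00114) to a mean ratio of 0.282 ± 0.0704 (SD, n = 3) against 1 ± 0.196 in sham liver. Vsig4, a complement receptor, fell by 1.54 ± 0.32, Cd5l by 1.48 and Lyz2, lysozyme, by 1.41. Adgre4, a macrophage receptor, and Cybb, the NADPH oxidase subunit of phagocytes, fell by 1.49 and 1.48. The list test gave adjusted p = 6.01e-10 and fry adjusted p = 0.0241, with adjusted p = 0.514 with an estimated correlation. The mean was -0.87 without adult sham replicate 3, where 1 of 13 passed over all genes and 12 when adjusted over the list alone, and 1 passed over all genes without adult 90 min replicate 1. Endothelial markers had a mean of -0.22, with 1 of 14 falling over all genes and 2 falling and 1 rising when adjusted over the list alone (adjusted p = 0.185). With adult sham replicates 1, 2 and 3 and adult 90 min replicates 1, 2 and 3 left out in turn, 0, 1, 0, 0, 0 and 0 passed over all genes and 1, 2, 0, 2, 4 and 7 over the list alone, and the mean was -0.05 without adult 90 min replicate 1.

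The acute phase genes Saa2 and Saa1, which encode serum amyloid A and are near-identical in sequence, fell by 2.76 ± 0.73 and 2.27 ± 0.67 in adults at 90 min. Saa2 varied widely in sham liver, at 1 ± 1.27 (SD, n = 3), against 0.0801 ± 0.00981. Of 27 acute phase genes 3 fell over all genes and 7 when adjusted over the list alone, with a mean of -0.93 (adjusted p = 1.37e-05, and adjusted p = 0.696 with an estimated correlation). Without adult sham replicate 3 the mean was -0.61 and 0 passed either way. Without adult 90 min replicate 1, 2 or 3, 0 acute phase genes passed over all genes and 2, 2 and 1 over the list alone; 15 passed over the list alone without adult sham replicate 1 and 6 over all genes without adult sham replicate 2. Atf3, a stress-induced transcription factor, rose by 1.22 ± 0.32 and the inducible heat shock protein gene Hspa1a by 1.04 ± 0.25. Of the 36 immediate early and early stress genes 3 rose and 1 fell over all genes, and of the 19 heat shock genes 1 rose and 3 fell. Ccn1, a matricellular immediate early gene, rose by 0.82 ± 0.14 (adjusted p = 0.0114). The actin-severing gelsolin gene Gsn rose by 0.81, the matrix gene Dpt (dermatopontin) by 0.77, Sestd1 by 0.76, the kallikrein gene Klk1b5 by 0.82 and Dio3os by 1.00. Other chaperones fell, Hsp90aa1 by 1.34 and Hsp90b1 by 1.05. So did Xbp1, a factor of the unfolded protein response, by 0.90, Cxcl1 by 2.04, Srp54a by 1.55 and the heme-degrading enzyme gene Hmox1 by 0.67. In the proteasome 18 of 41 genes fell over all genes and 35 when adjusted over the list alone, with a mean of -0.51. Psmd7 fell by 0.90, Psma5 by 0.80 and Psma1 by 0.76 (list test adjusted p = 1.78e-11, fry adjusted p = 0.0431, and adjusted p = 0.688 with an estimated correlation). The 38 olfactory receptor genes had a median of 0.09 on these arrays. Among stellate markers Rgs5 fell by 0.80 and Colec11 by 0.67, 2 of 12 over all genes and when adjusted over the list alone. The list had a mean of -0.11 (adjusted p = 0.937). Collagen and matrix genes had a mean of 0.15, with 3 of 24 rising over all genes, Loxl1 by 0.55 among them, and 4 when adjusted over the list alone (adjusted p = 0.001, and adjusted p = 0.514 with an estimated correlation). Without adult sham replicate 3 or adult 90 min replicate 3, 2 matrix genes rose over the list alone, and over all genes 0 to 2 rose with any 1 array left out. The lipid desaturase gene Scd1 fell by 0.86 (adjusted p = 0.0114).

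In limma 1069 genes passed in adults at 90 min, 168 up and 901 down, and 4102 had an unadjusted p under 0.05; the arrays of either group did not overlap in 39.2% of genes, where chance gives 10%. The count was 312 without adult sham replicate 1, 7 without adult sham replicate 3, and 17, 91 and 266 without adult 90 min replicates 1, 2 and 3. The 18 proteasome genes became 4, 1, 1, 1 and 2 over all genes and 9 without adult sham replicate 2, against 26 to 34 over the list alone. Of 29 single genes tracked across settings, Cd163 alone passed with each of the 6 arrays left out. The 1069 genes kept a median of 92.2% to 106% of their log2 values with any 1 of the 6 arrays left out. The count was 3 after quantile normalization, 480 on log2(ratio + 16), 47 in the adult arrays alone, 2450 with the title code number as a covariate and 3026 with array weights.

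**Figure D1:**
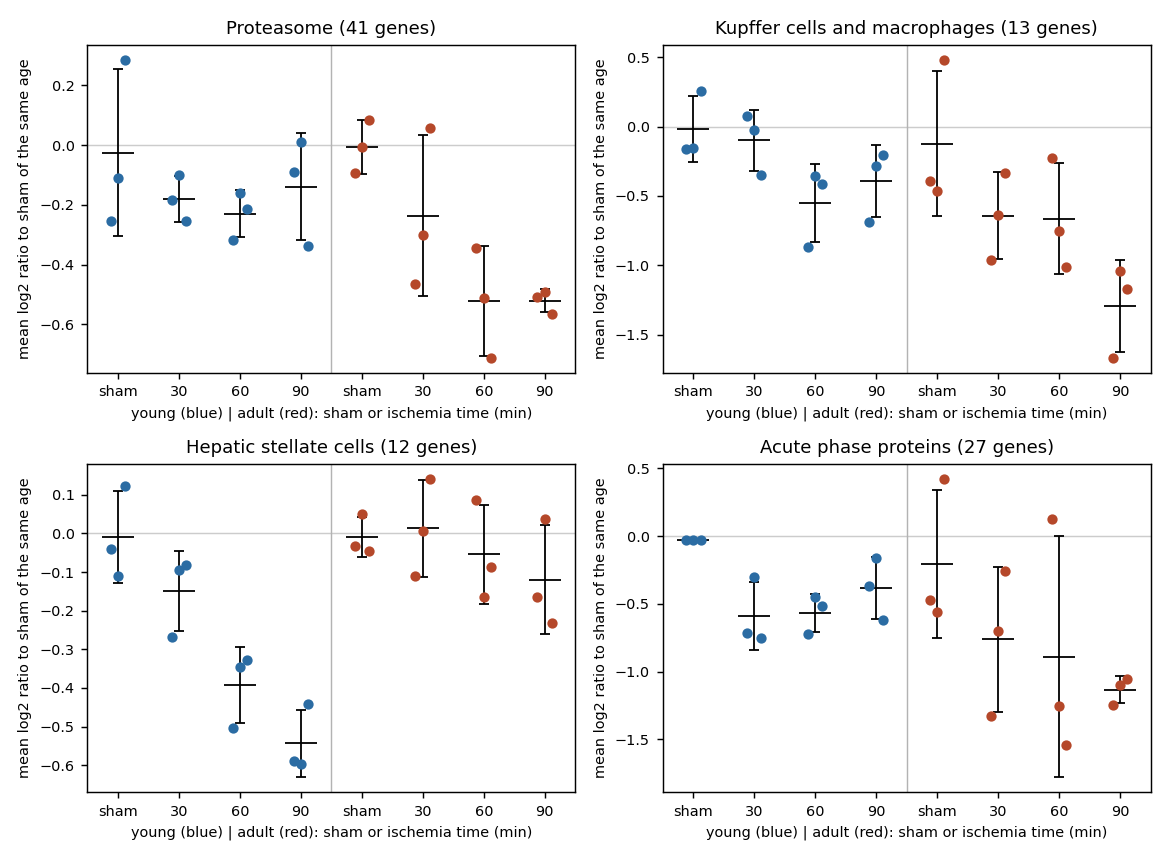
Mean log2 ratio of the genes of 4 lists (41 proteasome, 13 Kupffer cell, 12 hepatic stellate cell and 27 acute phase genes) in each array, by group; points are arrays and the black bar is the mean with the SD of 3 arrays. Kupffer cell genes lie lowest in adults at 90 min (mean log2 fold change -1.17) and stellate cell genes lowest in young mice at 90 min (-0.53).

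**Figure D2:**
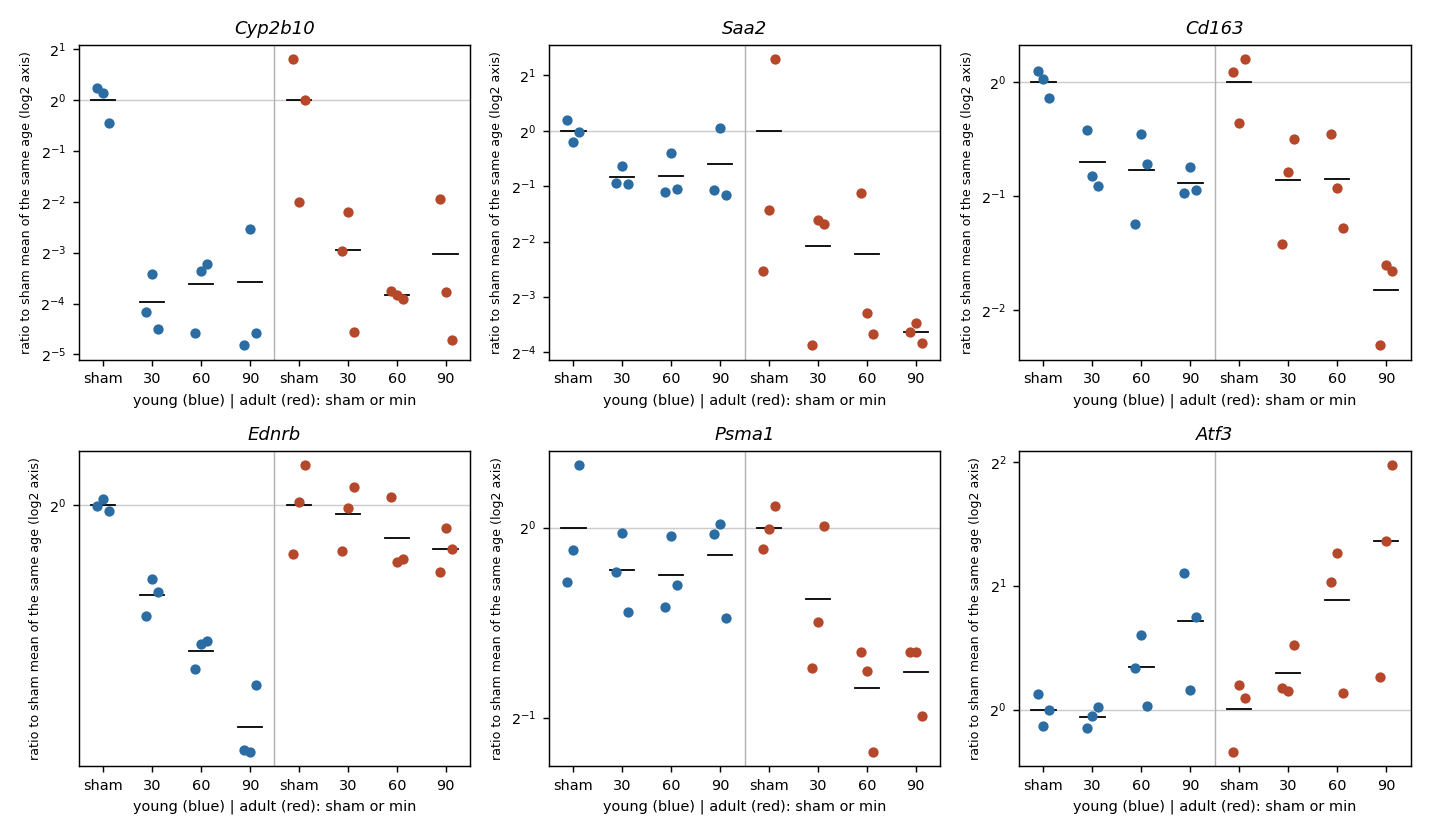
Ratio to the mean of the sham arrays of the same age for Cyp2b10, Saa2, Cd163, Ednrb, Psma1 and Atf3, on a log2 axis; points are arrays and the black line is the arithmetic mean of 3. Ednrb in young mice is at 0.788, 0.68 and 0.556 of sham after 30, 60 and 90 min, and Saa2 spreads widely between the adult sham arrays (SD 1.27).

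Whether the response differs between the ages was tested gene by gene as the adult response minus the young response. In limma 0 of 14351 genes passed at 30, 60 or 90 min, with 302, 978 and 1612 genes at an unadjusted p under 0.05. At 60 min the difference was -0.63 for Psma1 (adjusted p = 0.704) and -1.18 for Hspa5 (adjusted p = 0.704), and at 90 min it was -0.62 for Psma1 (adjusted p = 0.439) and -0.96 for Cd163 (adjusted p = 0.428). The mean of stellate cell markers fell less against sham in adults than in young mice at 90 min. The difference had a mean of 0.42, with 12 of 12 markers above 0. Of these 0 passed over all genes and 3 when adjusted over the list alone, with 5 without adult 90 min replicate 3. Pdgfra, a platelet-derived growth factor receptor, was at 0.65 ± 0.15 and Reln at 0.72 ± 0.22 (list test adjusted p = 1.08e-06, fry adjusted p = 0.0431, and adjusted p = 0.274 with an estimated correlation). Kupffer cell markers were lower in adults at 90 min by a mean of -0.80 with 13 of 13 below 0, C1qb at -1.14 among them, and -0.50 without adult sham replicate 3 (adjusted p = 5.56e-06, and adjusted p = 0.696 with an estimated correlation). Of these 0 passed over all genes and 5 when adjusted over the list alone, which became 0 without young sham replicate 1 or 2, young 90 min replicate 2 or 3, adult sham replicate 3 or adult 90 min replicate 1, and 3 without young sham replicate 3. The proteasome difference was -0.31 at 60 min and -0.40 at 90 min, with 0 of 41 genes passing over all genes or when adjusted over the list alone at either time (adjusted p = 1.37e-05 and 3.41e-08, and adjusted p = 0.696 at both times with an estimated correlation). The olfactory receptor median of this difference was 0.02 at 60 min and 0.11 at 90 min, with 31 of 38 above 0 at 90 min, a median that 223 of 100000 random sets of the same size reached. Array weights gave 1382 genes at 90 min, and the title code number as a covariate gave 1 gene at 60 min.

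Across genes, the log2 fold changes of the ages had a Pearson correlation of 0.611 at 30 min, 0.557 at 60 min and 0.359 at 90 min, with Spearman values of 0.556, 0.59 and 0.295. Genes are not independent replicates, so no p is given; the standard errors from leaving out 1 array at a time were 0.171, 0.317 and 0.379. The value at 60 min was 0.266 without young sham replicate 3, and that at 90 min was 0.0896 without young sham replicate 3 and 0.179 without young 90 min replicate 3. Gja4 fell at both ages after 60 min, where chance gives 0.196 shared falls. After 90 min Prkaa2 rose at both ages (chance 0.117) and 6 genes fell at both, where chance gives 1: Cyp2b10, Colec11, Rgs5, Gja4, Cd59a and Dnaja3. The last 2 of these, a complement inhibitor and a mitochondrial co-chaperone, were named after their values were seen. In adults these were -3.08 for Cyp2b10, -0.59 for Gja4 and 0.56 for Prkaa2. Of the genes that passed in adults, 91.2% had the same sign in young mice at 60 min and 82.2% at 90 min, against 72.4% and 58.5% of all genes. Tested together over the 3 times, 13 genes passed in young mice, 74 in adults and 0 for the age difference (730 at an unadjusted p under 0.05). The 13 became 2, 4 and 4 without young sham replicates 1, 2 and 3, 4 and 7 without young 30 min replicates 2 and 3, and 7, 7 and 22 without young 90 min replicates 1, 2 and 3. The 74 became 22 and 9 without adult sham replicates 1 and 3, and 822, 44 and 1282 without adult 30 min replicates 1, 2 and 3. They became 273, 7 and 12 without adult 60 min replicates 1, 2 and 3, and 6, 10 and 13 without adult 90 min replicates 1, 2 and 3.

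The immediate early genes Fos, Jun and Egr1 passed at no time in either age. Fos was at 1.46, 1.15 and 1.84 in young mice after 30, 60 and 90 min and at 1.33, 0.96 and 0.97 in adults, with an SE of 0.73. Jun was between 0.87 and 1.53, with an SE of 0.49, and Egr1 between 0.42 and 1.06, with an SE of 0.43. The albumin gene Alb, the hypoxia target Vegfa and the NF-kB inhibitor Nfkbia also passed in no comparison, at -0.24, -0.05 and -0.58 in adults at 60 min. The 20 glucocorticoid and circadian genes passed as a list in no comparison, while single clock genes moved widely between arrays: Dbp was at -2.43 in young mice at 30 and 90 min and at 1.19 in adults at 60 min, and passed in none of them.

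Other lists passed with the preset correlation and lost the call with an estimated one. In young mice at 30 min these were acute phase (-0.56), endothelial markers (-0.22), oxidative phosphorylation (-0.21), hepatocyte markers (-0.16) and the proteasome (-0.15), with adjusted p from 1.03e-05 to 0.019, and adjusted p = 0.696 to 0.718 with an estimated correlation. None of their genes passed over all genes, and 2 endothelial and 1 hepatocyte gene fell over the list alone. The proteasome fall depends on young sham replicate 3, where the list mean was 0.29. Young sham replicates 1 and 2 were at -0.25 and -0.11, and the 30 min arrays at -0.19, -0.10 and -0.25. The endothelial list lost its call with the title code as a block (adjusted p = 0.130) and with its number as a covariate (adjusted p = 0.143). At 60 min they were acute phase (-0.53), sterol and fatty acid synthesis (-0.41), cytochrome P450 (-0.32), endothelial markers (-0.30), NF-kB targets (-0.21), hypoxia and glycolysis (-0.20), the proteasome (-0.20), oxidative phosphorylation (-0.17), antioxidant genes (-0.14) and T and NK cell markers (0.09), with adjusted p from 4.09e-05 to 0.0491, and adjusted p = 0.605 to 0.748 with an estimated correlation. None of their genes passed over all genes, and 3 cytochrome P450, 2 NF-kB, 1 acute phase and 1 hypoxia gene fell over the list alone. The T and NK cell markers had a median of 0.10, as did the olfactory receptor genes on these arrays. The proteasome list means were -0.32, -0.16 and -0.21 in the 60 min arrays, so this fall too depends largely on young sham replicate 3. The 3 cytochrome P450 genes became 1 without young sham replicate 1 or 3. The antioxidant list lost its call after quantile normalization (adjusted p = 0.129) and with the block (adjusted p = 0.0668). At 90 min they were Kupffer cell markers (-0.37), acute phase (-0.35), cytochrome P450 (-0.32), immediate early genes (0.23), endothelial markers (-0.22) and oxidative phosphorylation (-0.14), with adjusted p from 0.000271 to 0.0246, and adjusted p = 0.696 to 0.802 with an estimated correlation. Of their genes only 1 cytochrome P450 gene passed over all genes, and over the list alone 4 immediate early genes rose and 2 fell, and 2 Kupffer, 2 endothelial and 1 cytochrome P450 gene fell. The 6 immediate early genes became 0 without young sham replicate 1 or 2 or young 90 min replicate 1 or 3, 2 without young sham replicate 3 and 11 without young 90 min replicate 2. That list lost its call with the block (adjusted p = 0.176) and after quantile normalization (adjusted p = 0.0702). With the title code number as a covariate the acute phase list (adjusted p = 0.0576) and the endothelial list (adjusted p = 0.305) lost theirs.

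In adults at 30 min the further lists were acute phase (-0.56), B and plasma cell markers (0.36), cytochrome P450 (-0.26), the proteasome (-0.23), heat shock proteins (-0.21), antioxidant genes (-0.20), hypoxia and glycolysis (-0.18), gluconeogenesis and urea cycle (-0.17), fetal liver genes (0.12), collagens (0.12), oxidative phosphorylation (-0.12) and hepatocyte markers (-0.12), with adjusted p from 9.01e-06 to 0.0404, and adjusted p = 0.274 to 0.834 with an estimated correlation. None of their genes passed over all genes, and over the list alone 1 collagen gene rose and 1 cytochrome P450 and 1 gluconeogenesis gene fell. The size of the acute phase fall depends on adult sham replicate 3, where the list mean was 0.42. Adult sham replicates 1 and 2 were at -0.47 and -0.56, and the 30 min arrays at -1.32, -0.70 and -0.26. The hypoxia list lost its call with every probe set on its own (adjusted p = 0.0519) and with the title code number as a covariate (adjusted p = 0.132), and the hepatocyte list with the block (adjusted p = 0.0657). At 60 min they were acute phase (-0.68), sterol and fatty acid synthesis (-0.63), Kupffer cell markers (-0.54, and -0.24 without adult sham replicate 3), gluconeogenesis and urea cycle (-0.46), fatty acid oxidation (-0.32), hepatocyte markers (-0.29), B and plasma cell markers (0.22), immediate early genes (0.16), T and NK cell markers (0.14), fetal liver genes (0.12) and collagens (0.09), with adjusted p from 0.0005 to 0.0206, and adjusted p = 0.315 to 0.702 with an estimated correlation. Over all genes 7 fatty acid oxidation, 4 sterol, 3 hepatocyte, 1 gluconeogenesis, 1 acute phase and 1 Kupffer gene fell, and over the list alone 11, 10, 7, 4, 1 and 1. In the immediate early list 1 gene rose and 2 fell, and 1 B cell, 1 fetal liver and 1 collagen gene rose over all genes. The olfactory receptor median was 0.11 on these arrays, against list medians of 0.16 for T and NK cells, 0.10 for fetal liver genes and 0.10 for collagens. Acute phase list means were 0.12, -1.25 and -1.54 in adult 60 min replicates 1, 2 and 3, so replicate 1 did not share the fall. The size of this fall also depends on adult sham replicate 3. The numbers of passing genes moved when adult sham replicates 1, 2 and 3 and adult 60 min replicates 1, 2 and 3 were left out in turn. Over all genes fatty acid oxidation gave 0, 1, 0, 7, 0 and 0, sterol synthesis 0, 1, 0, 2, 0 and 0, hepatocyte markers 0, 1, 0, 11, 0 and 0, gluconeogenesis 0, 1, 0, 3, 0 and 0 and the immediate early list 0, 5, 0, 4, 2 and 0. Over the list alone they gave 3, 8, 13, 10, 8 and 1; 16, 6, 1, 2, 10 and 0; 0, 3, 0, 16, 3 and 0; 1, 5, 1, 10, 1 and 1; and 2, 6, 2, 4, 2 and 7. At 90 min they were sterol and fatty acid synthesis (-0.41), oxidative phosphorylation (-0.36), gluconeogenesis and urea cycle (-0.35), heat shock proteins (-0.33), cytochrome P450 (-0.33), antioxidant genes (-0.31), hepatocyte markers (-0.21), fetal liver genes (0.19, with fry adjusted p = 0.0143), immediate early genes (0.14) and T and NK cell markers (0.11), with adjusted p from 5.69e-07 to 0.0196, and adjusted p = 0.195 to 0.702 with an estimated correlation. Over all genes 7 antioxidant, 5 oxidative phosphorylation, 3 heat shock, 3 cytochrome P450, 1 sterol and 0 gluconeogenesis genes fell, and over the list alone 8, 5, 8, 3, 1 and 5. In the immediate early list 3 rose and 1 fell over all genes, with 2 falling over the list alone, and 1 heat shock and 1 fetal liver gene rose. The olfactory receptor median was 0.09 on these arrays, against a median of 0.10 for T and NK cell markers and 0.21 for fetal liver genes. With adult sham replicates 1, 2 and 3 and adult 90 min replicates 1, 2 and 3 left out in turn, the antioxidant list gave 2, 5, 0, 0, 0 and 1 over all genes, oxidative phosphorylation 1, 1, 0, 0, 0 and 0, heat shock proteins 0, 4, 0, 0, 0 and 0, cytochrome P450 1, 3, 0, 1, 0 and 0, gluconeogenesis 0, 1, 0, 0, 0 and 0 and the immediate early list 1, 4, 0, 2, 1 and 3. Over the list alone they gave 5, 8, 5, 6, 9 and 7; 3, 0, 3, 2, 6 and 0; 5, 8, 6, 10, 5 and 3; 3, 3, 0, 4, 3 and 0; 0, 9, 0, 7, 0 and 0; and 3, 7, 2, 7, 6 and 4. With the block, cytochrome P450 (adjusted p = 0.0969), gluconeogenesis (adjusted p = 0.0534) and hepatocyte markers (adjusted p = 0.123) lost their calls. Markers of neutrophils, cholangiocytes and erythroid cells and genes of MHC class II antigen presentation passed as a list in no comparison, the last with a mean of -0.43 in adults at 90 min (adjusted p = 0.103).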

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

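The age differences in this part are listed because the list test passed with the preset correlation, and none of them passed with an estimated one. The tests of the clock genes, with and without single arrays, and of the Kupffer cell markers, the covariate of olfactory receptors, the number as a covariate at 90 min, the further random sets and the splits of the age correlation were chosen after the results were seen. So was the prediction on the source of the adult fold changes, written after the counts with arrays left out were known.

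At 30 min, the adult response minus the young one had a mean log2 value of -0.23 for heat shock proteins, 0.13 for cytochrome P450, 0.08 for oxidative phosphorylation, -0.28 for the cell cycle, 0.18 for collagens, 0.15 for T and NK cell markers, 0.36 for B and plasma cell markers, -0.44 for Kupffer cell markers and 0.16 for stellate cell markers (adjusted p = 0.315 to 0.834 with an estimated correlation). At 60 min it was 0.13 for immediate early genes, -0.57 for heat shock proteins, -0.53 for endoplasmic reticulum stress, -0.31 for the proteasome, -0.31 for antioxidant genes, -0.18 for cytochrome P450, -0.27 for oxidative phosphorylation, -0.14 for fatty acid oxidation, -0.37 for gluconeogenesis and urea cycle, 0.10 for fetal liver genes, 0.20 for collagens, 0.13 for endothelial markers, 0.34 for stellate cell markers and -0.22 for hepatocyte markers (adjusted p = 0.274 to 0.702 with an estimated correlation). At 90 min it was -0.37 for heat shock proteins, -0.36 for endoplasmic reticulum stress, -0.40 for the proteasome, -0.57 for acute phase, -0.23 for antioxidant genes, -0.22 for oxidative phosphorylation, -0.54 for sterol and fatty acid synthesis, -0.31 for gluconeogenesis and urea cycle, -0.34 for the cell cycle, 0.27 for collagens, -0.80 for Kupffer cell markers and 0.42 for stellate cell markers (adjusted p = 0.274 to 0.765 with an estimated correlation). With the first part of the title code as a block, 5 of these calls were lost: heat shock proteins (adjusted p = 0.560) and cytochrome P450 (adjusted p = 0.0941) at 30 min, fatty acid oxidation at 60 min (adjusted p = 0.0941), and gluconeogenesis (adjusted p = 0.0746) and the cell cycle (adjusted p = 0.324) at 90 min. With the title code number as a covariate cytochrome P450 (adjusted p = 0.258) and oxidative phosphorylation (adjusted p = 0.770) at 30 min and fetal liver genes at 60 min (adjusted p = 0.0744) lost theirs. After quantile normalization fetal liver genes at 60 min (adjusted p = 0.151) and gluconeogenesis at 90 min (adjusted p = 0.0771) lost theirs, and with arrays centred on their median fetal liver genes (adjusted p = 0.0581). Over all genes 0 members passed in any of these. Counts over the list alone could turn on single arrays: for heat shock proteins at 60 min the count was 0 without young sham replicate 1 and 14 without young sham replicate 3. Means could depend on single arrays too. For the cell cycle at 30 min, young 30 min replicate 1 had a list mean of 0.73, against 0.09 and 0.06 in replicates 2 and 3. Probe sets without a gene symbol passed as well, 1 in young mice at 30 min, 4 at 90 min, 623 in adults at 60 min and 429 at 90 min, of 10952.

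The fall of many genes in adult liver at 60 and 90 min has 3 explanations that were tested. Compression of the array scale could raise dim and lower bright probe sets: olfactory receptor genes had a median of 0.108 at 60 min in adults, with 28 of 38 above 0 and 3 passing, against 0.039 for the upper end of the middle 95% and 0.1196 for the highest of 1000 random sets. That highest value was the bound set in advance, and it turns on the draw: it lay below 0.108 in 86 of 100 further draws of 1000 sets, and 16 of 100000 sets reached 0.108. This explanation stays open. With that median as a covariate 5 genes passed at 60 min and 174 at 90 min, and the proteasome mean went from -0.52 to -0.36 and from -0.51 to -0.39, with 0 and 3 of its genes passing instead of 22 and 18. A single sham array could carry the counts, which fell to 4 without adult sham replicate 3. The 1712 genes kept 94.9% of their log2 values there. They were chosen on the same arrays for changes large against their spread, which makes a high kept share likely in advance. The share therefore cannot exclude a single sham array as the source of the fold changes, and this explanation stays open. The number in the second part of the title code also stays open: 1705 of the 1712 genes at 60 min and 1011 of the 1069 at 90 min stayed when it was a covariate, but it is 5 in each adult sham array, 4 in each at 60 min and 2, 2 and 6 at 90 min. No adult sham array shares a number with either group, and among these 3 groups it varies within 90 min alone.

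A score of 11 clock genes was lower after ischemia than in sham liver by 1.43 in young mice, and higher by 0.08 in adults. Single sham arrays move this: it was -2.25 without young sham replicate 3 and -0.95 without young sham replicate 2, and in adults -0.54 without sham replicate 2, 0.39 without sham replicate 1 and 0.38 without sham replicate 3. The score may follow whatever the number in the second part of the title code stands for: in young mice r = 0.83 over 12 arrays (permutation p = 0.00031, two-sided; 0.67 without the 2 arrays farthest out), and in adults r = 0.56 (permutation p = 0.0617). Within groups the exact one-sided p was 0.0741, where the smallest possible was 0.037, so this stays open. A response to ischemia also stays open, with a difference of -0.03 and a permutation p of 0.942 once the number was a covariate. Fitted within each age the difference was -1.03 in young mice and 1.23 in adults, and 5 of the 6 sham arrays share the number 5.

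Kupffer cell markers fell in adults at 90 min. The mean stayed at -0.866 or below with any adult sham array left out, so no single sham array is the whole source of the fall. The pattern was picked after the results were seen, which makes it likely in advance that a fall stays. A single sham array is therefore not excluded as the source of a part of it. The list mean was 0.48 in adult sham replicate 3, against -0.39 and -0.46 in adult sham replicates 1 and 2. A loss of non-parenchymal cells of every type alike would lower the Kupffer cell and endothelial lists alike. The Kupffer mean lay -0.946 (SE 0.132 over genes) from that of endothelial markers. With 1 of the 6 arrays left out the smallest difference was -0.649 (SE 0.142), without adult sham replicate 3, and the largest -1.10, without adult sham replicate 1. These SE take genes as replicates and leave out the spread between arrays. The difference argues against an equal loss on these arrays but does not exclude it. Fewer Kupffer cells, or less of these transcripts per cell, could each give the fall, and counting the cells on sections of the same lobes would separate them. Of the 13 markers 0 are held by another list, and the ratios keep no levels.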

How the results depend on the processing

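Each group has 3 arrays, and most counts moved with the processing. Of 87 named values that passed, 7 passed with any 1 array left out, 80 lost the call without at least 1 array, and 87 kept their sign; 0 reversed under the alternatives run on them, 21 passed after quantile normalization, 64 with the block, 46 on log2(ratio + 16), 74 with the number as a covariate and 86 with array weights. Except where stated, the cause was not tested. Not run, since the ratios keep no brightness, were no filter and a stricter filter on dim probe sets, the variance trend, and adult against young sham liver. With every probe set on its own 2 passed in young mice at 60 min and 126 in adults over the 3 times. After quantile normalization 7 passed in young mice at 60 min, 0 in adults at 60 min, 3 at 90 min and 0 over the 3 times. With the first part of the title code as a block 2 passed in young mice at 60 min, 4 at 90 min and 5 over the 3 times, and 278 in adults over the 3 times. With its second part as a covariate 2 and 16 passed in young mice at 60 and 90 min, 3200, 2450 and 1482 in adults at 60 min, 90 min and over the 3 times, and 1 for the age difference at 60 min. With array weights 304, 30, 869 and 485 passed in young mice (30, 60, 90 min, all times), 2350, 2924, 3026 and 2921 in adults, and 1382 for the age difference at 90 min. On log2(ratio + 16) 5 passed in young mice at 30 min, and 465, 480 and 9 in adults at 60 min, 90 min and over the 3 times. In the arrays of 1 age 46, 16, 66 and 39 passed in young mice, and 587, 47 and 1 in adults at 60 min, 90 min and over the 3 times. Of 108 list calls, 0 passed with an estimated correlation (lowest adjusted p = 0.0852) and 10 with fry; 106 kept call and direction with every probe set on its own, 104 after quantile normalization, 96 with the block, 108 with the mean of probe sets, 106 with arrays centred on their median and 100 with the number as a covariate, where 1 turned (sterol and fatty acid synthesis in young mice at 90 min). With 1 array left out the counts ran from 4 to 9, 1 to 6 and 2 to 52 in young mice at 30, 60 and 90 min, and from 0 to 89, 1 to 2177 and 7 to 806 in adults. They ran from 0 to 0, 0 to 1 and 0 to 0 for the age differences, and over the 3 times from 2 to 22 in young mice, 6 to 1282 in adults and 0 to 1 for the difference. The correlation of the ages ran from 0.449 to 0.670 at 30 min, 0.266 to 0.670 at 60 min and 0.0896 to 0.522 at 90 min.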

Other observations

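The comparisons between ischemia times, the test of olfactory receptors against the proteasome per array, the splits of the age correlation and those within the title code were chosen after the results were seen.

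Between ischemia times, added after the data were seen, stellate cell markers in young mice were lower at 90 than at 30 min by a mean log2 value of -0.39, with 11 of 12 below 0 and 8 passing when adjusted over the list alone (adjusted p = 0.00774 with an estimated correlation, fry adjusted p = 0.00583, over 18 tests). The 18 tests cover the proteasome, Kupffer cell and stellate cell lists alone, picked from 27 lists after the results against sham were seen. The adjusted p values do not account for that choice. Stellate means were -0.13 in adults at 90 against 30 min and -0.15 in young mice at 90 against 60 min (adjusted p = 0.596 and 0.334 with an estimated correlation). Kupffer cell markers in adults were lower at 90 than at 60 min by -0.63, with 13 of 13 below 0 and 9 passing over the list alone (adjusted p = 0.0772 with an estimated correlation). In limma 0 genes passed between any 2 times, with 741, 622 and 1339 at an unadjusted p under 0.05 in young mice (60 against 30, 90 against 30, 90 against 60 min) and 1260, 1086 and 458 in adults. For adults at 90 against 30 min other settings gave 160 genes with array weights, 6 with the block, 4 with arrays centred on their median, 4 with every probe set on its own, 3 with the title code number as a covariate, 8 with the olfactory receptor median as a covariate and 3 without adult 30 min replicate 1. Array weights gave 11 in young mice at 90 against 30 min, 2 at 90 against 60 min and 5 in adults at 60 against 30 min. Every probe set on its own gave 2 in adults at 90 against 60 min, and 1 gene passed in young mice at 60 against 30 min without young 60 min replicate 3 and at 90 against 60 min without young 90 min replicate 3.

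Across arrays, the proteasome mean fell as the olfactory receptor median rose in adults (r = -0.79, 12 arrays, permutation p = 0.00227, two-sided, 4 relations tested) and in young mice r was -0.54 (permutation p = 0.0719), while the Spearman values were -0.79 (permutation p = 0.00341) and -0.76 (permutation p = 0.00675). Without the 2 arrays whose olfactory receptor median lay farthest from the median of all, r was -0.83 in adults and -0.41 in young mice. Without the 2 arrays farthest from the mean in both values together it was -0.64 and -0.72. Within groups, with group means taken off, r was -0.85 in adults and -0.47 in young mice.

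Arrays were also regrouped at random, and the real grouping is counted among the splits that reach its own value. Of the 10 splits of 3 against 3 arrays a share under 0.05 cannot be reached: the real split and the highest other gave 8 and 0 genes in young mice at 30 min (1 split as large), 4 and 2 at 60 min (1), 26 and 25 at 90 min (1), 0 and 391 in adults at 30 min (10, as any split reaches 0), 1712 and 16 at 60 min (1) and 1069 and 11 at 90 min (1). The 391 genes came from the split that puts adult 30 min replicate 3 with adult sham replicates 1 and 3. Such a count points to a structure of the samples, whose source was not identified. For the age difference the real count is 0, which any split reaches (100 of 100 at each time and over the 3 times), so these splits say nothing about chance. The highest other gave 955, 998 and 1795 genes at 30, 60 and 90 min and 2304 over the 3 times. Over the 3 times 1 of 100 splits, the real one, reached the 13 genes of young mice (highest other 4). This share is under the 0.05 set in advance and argues against chance, but does not exclude it. The 13 became 5 with the first part of the title code as a block and 2, 4 and 4 without young sham replicates 1, 2 and 3. Of 100 splits within that part of the code 1 reached the 13 genes (highest other 11), and 1 the 5 genes of the fit with the block (highest other 2). In adults 7 of 100 splits reached the 74 genes (highest other 2824), so chance is not excluded. The split with 2824 genes again puts adult 30 min replicate 3 with adult sham replicates 1 and 3, and the source of this structure was not identified either. For the correlation of the ages 1, 3 and 19 of 100 splits were as high as the real 0.611, 0.557 and 0.359 at 30, 60 and 90 min (highest other 0.560, 0.717 and 0.533). At 60 min the share was under 0.05, but another split exceeded the real value. Its standard error from leaving out 1 array at a time was 0.317, so chance is not taken as excluded there. At 30 min only the real split was as high, and the standard error was 0.171. This argues against chance there but does not exclude it. The splits ignore both parts of the title code, so a source shared through either is not addressed. Only the second part has values in common between the ages, with the number 5 in 5 of the 6 sham arrays.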
